A study of Mus musculus with 48 samples.

How the data were processed

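RNA of liver and of a gut sample, written "Gut (DI)" in the labels, was measured on 48 expression arrays, 24 per tissue. Per the labels, recipient mice ate a normal diet and received faecal transplants from donors on a high-fat diet (HF), a ketogenic diet (KD) or normal chow (NC), and tissue was taken at zeitgeber time ZT0 or ZT12 of a 12 hr light and 12 hr dark cycle. Each of the 12 groups of tissue, donor diet and time held 4 arrays. The mice were male C57BL/6J, and RNA was extracted with TRIzol and cleaned on RNeasy columns. Nothing but titles and labels says that the samples are separate animals, so the p-values may measure technical spread. The titles give 33 mouse codes, of which 15 appear in both tissues; the tissues were fitted apart. The number in a title was treated as a replicate number that pairs nothing: in liver, the deviations of 12 pairs of arrays that share a number had a mean correlation across genes of -0.075, and in gut 16 such pairs had 0.001. Samples are named by tissue, donor diet, time and that number.

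The deposited value table holds linear intensity per transcript cluster for 35556 clusters, computed with PLIER per the submitters' processing notes, with no version given in the sources used here. Its values were above 0 and reached 17315 intensity units. The 8 deposited comparison tables, each of HF or KD against NC donors at 1 tissue and time, hold the same intensity values for the clusters with a gene symbol. Per the file headers they also hold a p-value per cluster with Bonferroni and BH columns, a ROC.y score between 0 and 1, and a ratio of group means (ratioMean). The column names are those of a regularised Bayesian statistic; the tool is not given in the sources used here. The deposited Bonferroni column equals the ROC.y score times the number of clusters, and the deposited BH column lay below 0.05 for 23807 to 23810 clusters in 5 tables and for 0 in 3, so adjusted p-values were recomputed from the authors' p-value column.

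Of the clusters, 23811 (67.0%) carry a symbol in the authors' tables. Symbols were brought up to date through accessions (21429 clusters), current symbols (1862) or older names (220), and 300 kept the authors' symbol unmatched. No coordinates are printed because the files name no genome build. Where several clusters named 1 gene, the one with the highest mean in the tissue was kept, which left 20702 genes; the 11745 clusters without a name were fitted separately. Array medians spanned 0.209 log2 units in liver and 0.108 in gut, which exceeded the limit fixed in advance, so log2(intensity + 16) was quantile normalised within each tissue.

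Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 groups, 18 residual degrees of freedom, two-sided, no intensity trend), with Benjamini-Hochberg adjustment over the genes of a tissue and a threshold of 0.05. Each tissue had 11 contrasts: HF against NC, KD against NC and HF against KD at each time, ZT12 against ZT0 for each donor diet, and the change of each donor effect between the times. With no difference at all, a share of 0.05 of the 20702 genes is expected at unadjusted p under 0.05 in a contrast. Lists of genes and of cell type markers, 39 of them with at least 5 measured members, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. An adjusted p of a list is from camera with the preset correlation unless stated. The mean of each list was also compared between 2 groups by an exact two-sided permutation of the arrays. Its p-values were not adjusted over the 39 lists, and 0.0286 is the smallest that 4 against 4 arrays allow. Such a p-value alone therefore does not single out a list. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9. The groups, lists, tests, named-gene rule and most alternatives were fixed before the data were examined.

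Genes are named by 4 criteria: the 10 highest and 10 lowest log2 fold changes among genes past the threshold; where fewer than 10 passed, the 5 highest and 5 lowest among genes at unadjusted p under 0.001, or 0.01 if that gave fewer than 10; up to 4 members of each list at unadjusted p under 0.01; and all members of the clock and PPARγ lists. Predicted genes, unnamed clones, small RNAs, olfactory receptors and antigen receptor segments were passed over in the first 2 criteria; of counts of 5 or fewer, members were named after their values were seen.

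The alternatives were the values without the quantile step, an offset of 1 in place of 16, no dim genes, only the groups compared, an intensity trend with a robust prior, array weights, all clusters singly, a block for the replicate number, the authors' table values, and leaving out each array. After the data were seen, a lymphoid marker covariate in gut, donor effects over both times, and the lists without liver KD ZT0 replicate 7 were added. The fit was tested on simulated data, in which 50 genes at each fold were changed in the HF arrays at ZT0: in liver 11 were called at 1.2-fold, 45 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, and in gut 12, 43, 49 and 50, with 5 and 2 false calls. Errors were drawn independently for each gene, with 200 genes changed at once. Outlying arrays and differences in tissue composition, which move many genes together, were left out. The share of changes found in the real data may be lower. The number of arrays limits the precision. Values are log2 fold changes ± SE with n = 4 arrays per group unless stated. A few single-gene results are not reported here.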

Results

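Liver and gut transcripts were profiled in normally fed mice that had received faecal transplants from HF, KD or NC donors, with tissue taken at ZT0 and ZT12. The series title names PPARγ and the liver circadian clock, so the comparisons address whether the donor's diet changed gene expression, the time-of-day difference of clock genes, or the genes around PPARγ. Each tissue, donor diet and time had 4 arrays. Median intensity per array lay between 88.2 and 104.4 units in liver and between 124.9 and 135.8 units in gut. The largest component of variation separated the times in liver: its score, holding 33.9% of the variance, was between 8.25 and 20.56 in the 12 arrays of ZT0 and between -19.15 and -11.02 in the 12 arrays of ZT12. In gut the first component held 22.2% and the times overlapped along it: the NC arrays of ZT12 lay between -4.94 and 2.36, and the ZT0 arrays reached up to -0.98.

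Clock genes differed between ZT12 and ZT0 in the liver of all 3 donor groups. Dbp (transcript cluster 10553092), a clock output transcription factor, rose by 4.45 ± 0.13 with NC donors, 4.31 ± 0.13 with HF donors and 4.15 ± 0.13 with KD donors on the log2 scale. Per3 rose by 3.01 ± 0.11, 3.14 ± 0.11 and 3.12 ± 0.11 in the same order. Arntl, which encodes the core activator BMAL1, fell (-3.35 ± 0.19, -3.01 ± 0.19 and -3.31 ± 0.19), and its relative Npas2 fell (-4.86 ± 0.26, -5.32 ± 0.26 and -5.02 ± 0.26). Of the 20 clock genes, 14 rose and 5 fell with NC donors, 13 and 5 with HF donors, and 12 and 5 with KD donors. Adjusted over the list alone, the counts were 14 and 5, 14 and 5, and 15 and 5. Nr1d1, encoding the repressor REV-ERBα, at 0.35 ± 0.27, 0.48 ± 0.27 and 0.62 ± 0.27, passed over all genes in none of the groups, and adjusted over the list alone with KD donors (adjusted p = 0.031). The shift of the list as a whole had adjusted p = 2.4e-09, 1.3e-08 and 6.9e-10, and adjusted p = 0.00067, 0.0011 and 0.00047 with an estimated correlation.

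**Figure D1:**
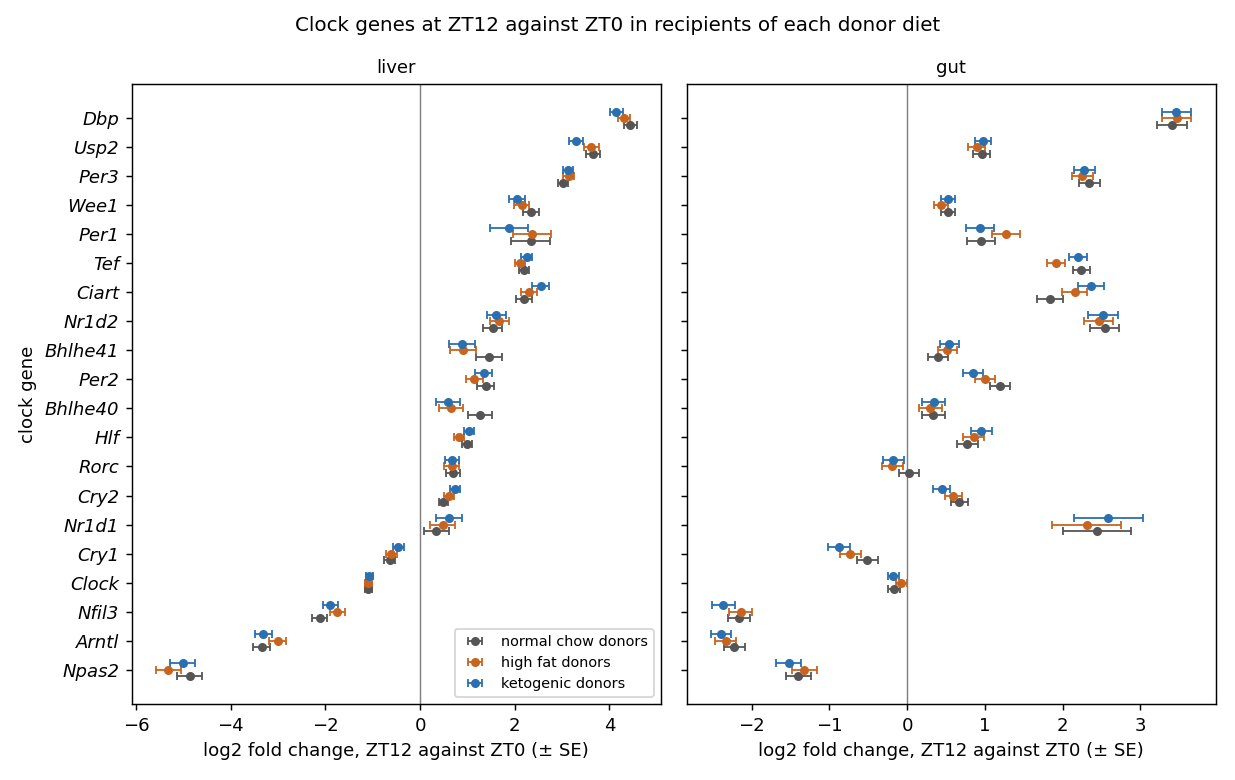
Difference between ZT12 and ZT0 (horizontal axis, log2 fold change; error bars SE, n = 4 arrays per group) of the 20 clock genes (vertical axis) in liver and in gut, with 1 point per donor diet. The points of the donor diets lie near each other for most genes, from Npas2 in liver, between -5.32 and -4.86, to Dbp in liver, between 4.15 and 4.45.

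Metabolic genes moved with time of day as well. Por, which supplies electrons to cytochrome P450 enzymes, rose by 2.33 ± 0.16, 2.15 ± 0.16 and 1.84 ± 0.16 in the liver of NC, HF and KD recipients, and Alas1, the first enzyme of haem synthesis, by 2.59 ± 0.27, 1.87 ± 0.27 and 1.76 ± 0.27. The sterol exporter gene Abcg5 rose by 0.87 ± 0.10, 1.02 ± 0.10 and 1.09 ± 0.10. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.99 ± 0.38 with NC donors. Genes that fell included Pdk4, an inhibitor of pyruvate oxidation (-2.73 ± 0.37, -2.02 ± 0.37 and -2.27 ± 0.37), the fatty acid elongase Elovl3 (-2.59 ± 0.26, -2.30 ± 0.26 and -2.40 ± 0.26) and Chka, which starts phosphatidylcholine synthesis (-2.59 ± 0.15, -2.89 ± 0.15 and -2.78 ± 0.15). Of 23 unfolded protein and integrated stress response genes, 12, 12 and 13 fell, among them the chaperone Pdia4 (-0.83 ± 0.10, -0.69 ± 0.10 and -0.75 ± 0.10). Adjusted over the list alone 14 fell in each group. That list had adjusted p = 2.2e-09, 7.1e-10 and 2.3e-10, and adjusted p = 0.20, 0.13 and 0.14 with an estimated correlation. Heat shock genes such as Hsp90aa1 (-0.61 ± 0.14, -0.84 ± 0.14 and -1.04 ± 0.14) also fell, 5, 7 and 9 of 15, while 1, 1 and 2 rose, and 5, 7 and 7 of 27 drug metabolism genes rose. The lists had adjusted p = 0.025, 0.00030 and 1.0e-05, and 0.025, 0.00012 and 0.00031, but adjusted p = 0.60, 0.30 and 0.14, and 0.60, 0.13 and 0.14 with an estimated correlation. By fry, which asks whether a list's genes move one way, these 3 lists passed in all 3 groups, the least firmly the heat shock list with NC donors at adjusted p = 0.043. Markers of sinusoidal endothelium were lower at ZT12, with median log2 fold changes of -0.23, -0.20 and -0.11 and adjusted p of 0.016, 0.029 and 0.025, but adjusted p = 0.60, 0.98 and 0.57 with an estimated correlation. With a block for the replicate number these medians were positive, at 0.26, 0.10 and 0.04. That block ties the liver times together through KD ZT0 replicate 7 alone, the only ZT0 array whose number recurs at ZT12. Without NC ZT0 replicate 6 or NC ZT12 replicate 7 the heat shock list with NC donors had adjusted p = 0.058 and 0.066. Its median of -0.44 with HF donors was -0.26 without HF ZT0 replicate 3, and that of -0.43 with KD donors was -0.68 without KD ZT0 replicate 5. The drug metabolism list with NC donors had adjusted p = 0.074 without NC ZT0 replicate 5 and 0.087 without NC ZT12 replicate 8, and with KD donors its median of 0.165 was 0.072 without KD ZT0 replicate 7 and 0.103 without KD ZT12 replicate 13. The endothelium list with NC donors had a median of -0.176 with adjusted p = 0.0503 without NC ZT0 replicate 5. With HF donors it had adjusted p = 0.11, 0.11 and 0.10 without HF ZT0 replicate 4 and HF ZT12 replicates 7 and 10. With KD donors it had adjusted p = 0.099 and 0.091 without KD ZT0 replicates 3 and 5, and a median of -0.26 without KD ZT0 replicate 7.

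In liver, 1882 genes differed between the times with NC donors (877 higher and 1005 lower at ZT12), 1626 with HF donors (654 and 972) and 1790 with KD donors (690 and 1100). Of the 2983 genes called in any group, 839 were called in all 3 with the same direction, 337 higher and 502 lower, and none was called in opposite directions. The changes correlated between donor groups at r = 0.827 for NC and HF, 0.792 for NC and KD, and 0.814 for HF and KD, across genes, which are not independent replicates. Being called in 1 group alone, as 1507 genes were, does not show a difference between groups. That difference was tested directly and is given with the donor comparisons. With a block for the replicate number the counts were 383, 288 and 348. Only KD ZT0 replicate 7 has a number that recurs at ZT12, so these blocked counts rest on that array. With array weights the time counts were 3178 for NC and 2464 for HF donors. With KD donors 806 genes passed when only the 2 groups compared were fitted.

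**Figure D2:**
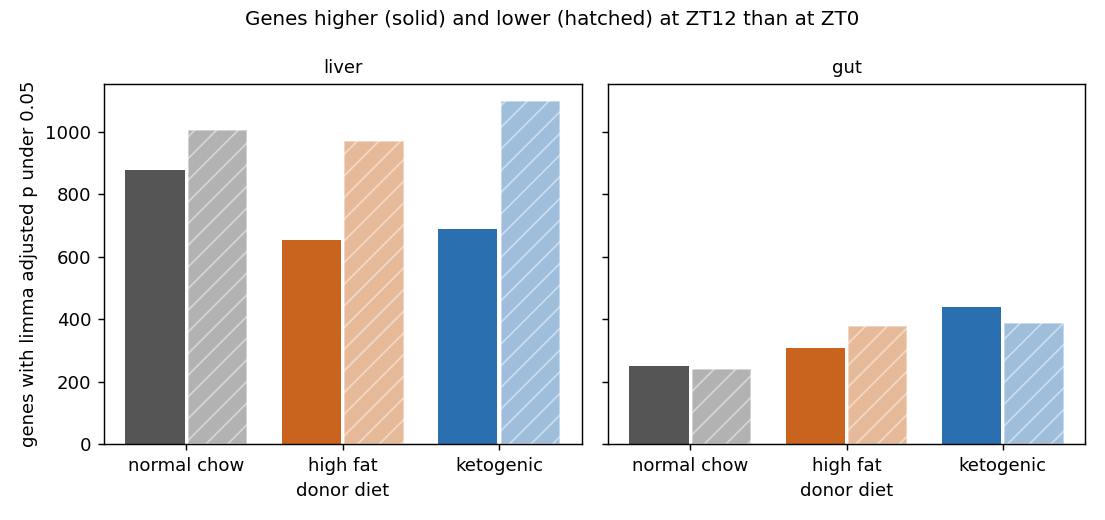
Number of genes past the limma threshold (vertical axis) between ZT12 and ZT0 for each donor diet in liver and gut, higher at ZT12 in solid bars and lower in hatched bars. The liver bars lie between 654 and 1100 genes and the gut bars between 242 and 438 genes.

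Clock genes changed in gut too. Dbp rose by 3.40 ± 0.19 with NC donors, 3.47 ± 0.19 with HF donors and 3.46 ± 0.19 with KD donors, Nr1d1 by 2.44 ± 0.44, 2.31 ± 0.44 and 2.59 ± 0.44, and Per3 by 2.34 ± 0.13, 2.25 ± 0.13 and 2.28 ± 0.13. Arntl fell (-2.22 ± 0.13, -2.33 ± 0.13 and -2.39 ± 0.13), and so did Nfil3, a repressor of Dbp targets (-2.16 ± 0.15, -2.14 ± 0.15 and -2.36 ± 0.15). Of the 20 genes, 12 rose and 4 fell with NC donors and 13 and 4 with HF and with KD donors. Adjusted over the list alone, the counts were 14 and 5, 13 and 4, and 14 and 5. Clock itself, at -0.17 ± 0.07, -0.07 ± 0.07 and -0.18 ± 0.07, did not pass over all genes. The list had adjusted p = 8.4e-13, 5.6e-10 and 2.8e-08, and adjusted p = 0.012, 0.038 and 0.085 with an estimated correlation.

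All 22 cholesterol synthesis genes were higher in gut at ZT12 with each donor diet. The median log2 fold changes were 0.59, 0.41 and 0.70, and 10, 3 and 17 passed the threshold. Adjusted over the list alone, 21, 16 and 21 rose. Stard4, a sterol carrier, rose by 0.39 ± 0.07, 0.41 ± 0.07 and 0.51 ± 0.07. The list had adjusted p = 6.2e-21, 9.5e-11 and 9.6e-22, and adjusted p = 0.20, 0.52 and 0.14 with an estimated correlation. An exact permutation test of its mean over arrays gave p = 0.0286 for each donor diet, the smallest that 4 against 4 arrays allow. Transporter genes that rose included the fructose transporter Slc2a5 (2.16 ± 0.24, 1.24 ± 0.24 and 1.62 ± 0.24), the glucose transporter Slc5a1 (0.69 ± 0.10, 0.42 ± 0.10 and 0.53 ± 0.10) and the amino acid transporter Slc6a19 (0.72 ± 0.11, 0.58 ± 0.11 and 0.53 ± 0.11). In total 7, 5 and 6 of 27 nutrient absorption genes rose. The list's adjusted p was 6.6e-05, 0.0090 and 0.027, against adjusted p = 0.63, 0.62 and 0.73 with an estimated correlation. Its medians were small, at 0.109, 0.060 and 0.054, and depended on single arrays. The HF median was -0.042 without HF ZT12 replicate 12 and -0.038 without HF ZT0 replicate 5 (adjusted p = 0.31 and 0.21), 0.021 without HF ZT0 replicate 4, and between 0.091 and 0.136 without HF ZT0 replicates 1 and 2 or HF ZT12 replicates 9 and 10. The NC median was 0.006 without NC ZT0 replicate 4 and 0.064 without NC ZT12 replicate 12. The KD median was 0.013, 0.030 and 0.015 without KD ZT0 replicates 5 and 6 and KD ZT12 replicate 10 (adjusted p = 0.17, 0.084 and 0.067), 0.035 and 0.033 without KD ZT0 replicate 1 and KD ZT12 replicate 13, and 0.141 without KD ZT0 replicate 4. The drug efflux genes Abcb1a (1.61 ± 0.15, 1.47 ± 0.15 and 1.32 ± 0.15) and Abcc2 (1.24 ± 0.27, 1.36 ± 0.27 and 1.25 ± 0.27) rose, and so did the metallothionein Mt2 (1.52 ± 0.40, 2.10 ± 0.40 and 1.67 ± 0.40). G6pc, the last step of glucose release, fell by 2.12 ± 0.46 with HF donors and by 2.50 ± 0.46 with KD donors. Of 23 cell cycle genes, 3 fell with HF donors (adjusted p = 1.0e-08, and adjusted p = 0.52 with an estimated correlation). B and plasma cell markers had a median of 1.25 with NC donors and of -1.71 with KD donors, and none of the 7 passed the threshold in either group. The list's adjusted p was 0.021 and 0.00062, and adjusted p = 0.65 and 0.60 with an estimated correlation. The NC median was 0.890, 0.793 and 1.118 without NC ZT0 replicates 4 and 6 and NC ZT12 replicate 12 (adjusted p = 0.23, 0.17 and 0.11).

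The gut totals were 494 genes with NC donors (252 higher and 242 lower), 687 with HF donors (309 and 378) and 826 with KD donors (438 and 388). All 3 groups shared 229 genes with the same direction, 127 higher and 102 lower, of 1332 called in any group. The correlations of the changes across genes were 0.567 for NC and HF, 0.360 for NC and KD, and 0.707 for HF and KD. Liver and gut shared 63 of the genes called in all 3 donor groups, 61 of them in the same direction (27 higher and 34 lower), where 9.28 would be expected if the tissues' calls were independent. By the titles 15 mice gave arrays of both tissues, so the calls do not all come from separate mice. Dbp, Per1, Per2, Per3, Tef, Hlf, Ciart, Wee1, Arntl, Npas2, Nfil3 and Cry1 were among the genes shared. Single arrays mattered in gut. The NC count was 327 without NC ZT0 replicate 4 and 308, 287 and 317 without NC ZT12 replicates 10, 11 and 12. The HF count was 362 and 396 without HF ZT0 replicates 4 and 5 and 387 and 311 without HF ZT12 replicates 8 and 12. The KD count was 349 without KD ZT0 replicate 4 and 480, 415, 412 and 518 without KD ZT12 replicates 8, 10, 12 and 13. Fitting only the groups compared gave 173 genes with NC donors and 190 with HF donors, array weights gave 1382 with KD donors, and the lymphoid marker covariate 354 with KD donors.

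PPARγ and its fat-storage targets differed between the times in few members. In liver, Plin2, a lipid droplet coat protein, fell (-0.61 ± 0.11, -0.46 ± 0.11 and -0.45 ± 0.11) with NC, HF and KD donors. Lpl, which releases fatty acids from lipoproteins, fell by 0.87 ± 0.17 with NC donors and 0.93 ± 0.17 with KD donors, and the lipid droplet gene Cidec rose by 0.33 ± 0.08 with NC donors and 0.48 ± 0.08 with HF donors. Fabp4 fell by 0.34 ± 0.08 with HF donors and 0.40 ± 0.08 with KD donors. In all, 3 of 20 members passed in each donor group, and adjusted over the list alone 3, 5 and 3. Pparg itself (transcript cluster 10540897) was at 0.24 ± 0.27, 0.41 ± 0.27 and 0.15 ± 0.27 in liver. In gut Pparg rose by 0.44 ± 0.12 with KD donors (adjusted p = 0.044) and was at 0.43 ± 0.12 and 0.42 ± 0.12 with NC and HF donors (adjusted p = 0.066 and 0.058). It was the only member called, and leaving out any 1 of 7 of the 8 KD arrays, all but KD ZT12 replicate 10, ended the call. With the replicate block, which ties the liver times together through KD ZT0 replicate 7 alone, 1, 0 and 0 of the liver members passed.

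By limma no clock gene and no member of the PPARγ list passed the threshold between recipients of HF or KD and of NC donors, in liver or gut, over all genes or adjusted over the list alone. By the authors' p-values 1 member passed after Benjamini-Hochberg adjustment: Aqp7, a glycerol channel, for KD against NC donors in gut at ZT12 (adjusted p = 0.034, ratio 1.388), where limma gave 0.51 ± 0.29 with adjusted p = 0.63. At ZT0 the clock genes of liver lay between Ciart at -0.31 ± 0.17 and Bhlhe40 at 0.32 ± 0.25 for HF against NC donors, and between Ciart at -0.44 ± 0.17 and Per1 at 0.40 ± 0.40 for KD against NC donors. The Per1 value leaned on KD ZT0 replicate 7, where Per1 was at 8.51 against a mean of 6.64 in the 11 other ZT0 arrays. At ZT12 they lay between Bhlhe41 at -0.51 ± 0.28 and Arntl at 0.32 ± 0.19 for HF, and between Bhlhe41 at -0.56 ± 0.28 and Cry2 at 0.13 ± 0.10 for KD. Pparg was 7.58 ± 0.35 in NC, 7.90 ± 0.36 in HF and 7.56 ± 0.25 in KD recipients at ZT12 (mean log2 intensity ± SD, n = 4 arrays), a difference of 0.32 ± 0.27 between HF and NC. In gut Pparg differed by 0.10 ± 0.12 for HF and -0.04 ± 0.12 for KD at ZT12, and the clock gene with the largest gut difference was Tef, at 0.37 ± 0.11 for HF at ZT0. The liver medians of the PPARγ list were 0.02 and 0.05 for HF at ZT0 and ZT12 and 0.01 and 0.01 for KD. By limma 0 liver genes passed in these 4 comparisons, with 1020 and 927 genes at unadjusted p under 0.05 for HF at ZT0 and ZT12, and 1079 and 827 for KD. These counts lie near or below the share of 0.05 of the 20702 genes expected with no difference, so they do not show changes below the threshold.

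Lipid synthesis genes lay mostly above the NC level in the liver of recipients of both other diets, without passing singly. Fatty acid and triglyceride synthesis genes were higher in 19 of 20 members for HF at ZT0 (median 0.13, adjusted p = 0.0027) and in 17 of 20 for KD at ZT12 (median 0.20, adjusted p = 0.0013), but had adjusted p = 0.65 and 0.99 with an estimated correlation. The HF median at ZT0 was -0.03 without HF ZT0 replicate 2, 0.225 without HF ZT0 replicate 3 and -0.055 with the replicate block, and the KD median at ZT12 was 0.112 without KD ZT12 replicate 12 (adjusted p = 0.17). The cholesterol synthesis list had medians of 0.17 for KD at ZT0, 0.15 for KD at ZT12 and 0.15 for HF at ZT12 (adjusted p = 0.0058, 0.035 and 0.019; adjusted p = 0.72, 0.99 and 0.84 with an estimated correlation), and with the block the last was -0.02. These medians rested on single arrays as well. For KD at ZT0 the median was 0.094 without NC ZT0 replicate 1 (adjusted p = 0.12) and 0.260 without NC ZT0 replicate 5. For KD at ZT12 it was 0.068, 0.055, 0.067 and 0.104 without NC ZT12 replicates 8 and 11 and KD ZT12 replicates 12 and 13 (adjusted p = 0.40, 0.29, 0.40 and 0.25), and 0.270 and 0.221 without NC ZT12 replicate 13 and KD ZT12 replicate 8. For HF at ZT12 it was 0.093, 0.097, 0.118 and 0.049 without NC ZT12 replicates 8 and 11 and HF ZT12 replicates 7 and 9 (adjusted p = 0.29, 0.25, 0.37 and 0.71), and 0.235 and 0.237 without NC ZT12 replicate 13 and HF ZT12 replicate 10. Interferon-stimulated genes were lower with HF donors at ZT12 in all 29 members (median -0.21, adjusted p = 7.9e-08, and adjusted p = 0.84 with an estimated correlation). At ZT0 all 8 liver macrophage markers were lower with HF than with NC donors (median -0.40), beside acute phase genes (median -0.19). Their adjusted p was 3.6e-05 and 0.0030, and adjusted p = 0.65 for both with an estimated correlation. Without NC ZT0 replicate 5 the medians were -0.245 and -0.121, the latter with adjusted p = 0.24, and without HF ZT0 replicate 2 the acute phase list had adjusted p = 0.055. NC ZT0 replicate 5 was also the highest of its group in Paneth cell (7.77), goblet cell (7.579) and absorptive enterocyte markers (9.402). Whether it held RNA of gut was not tested. Single genes that did not pass included Nr4a1, an immediate early nuclear receptor (-0.51 ± 0.11, adjusted p = 0.79), and Hamp, the iron hormone hepcidin (0.70 ± 0.21), for HF at ZT0, the water channel Aqp8 (0.77 ± 0.24) for HF at ZT12, Foxd4 (0.54 ± 0.11) for KD at ZT0, and Clvs2 (0.34 ± 0.06, adjusted p = 0.18) for KD at ZT12. Over both times together, 8 arrays against 8, Clvs2 rose by 0.28 ± 0.04 with KD donors (adjusted p = 0.020), a comparison added after the data were seen. It was the only gene called for KD, and 0 passed by limma for HF (1420 at unadjusted p under 0.05). The KD count was 0 under 5 other settings and without 1 of 11 of the 16 arrays, KD ZT0 replicate 7 among them. At ZT12 alone Clvs2 passed with an offset of 1 (adjusted p = 0.026) or with array weights (adjusted p = 0.017).

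HF and KD recipients were also set against each other in liver. At ZT12, 27 of 29 interferon-stimulated genes were lower with HF than with KD donors, at a median of -0.29, with Gbp4 at -0.84 ± 0.29 and Gbp5 at -0.66 ± 0.23. Much of this lay in 1 array: without KD ZT12 replicate 10 the median was -0.133, with adjusted p = 0.00017. All 9 stellate cell and fibroblast markers were higher, at a median of 0.21 and an unadjusted exact permutation p of 0.0286 for their mean. The lists had adjusted p = 2.4e-18 and 1.5e-06, and adjusted p = 0.28 for both with an estimated correlation. Cidec was at 0.28 ± 0.08. It was 1 of the 20 PPARγ genes past the threshold adjusted over the list alone, and 0 passed over all genes. That list had a median of 0.06 with adjusted p = 0.031, and adjusted p = 0.37 with an estimated correlation. Its median was 0.064, 0.038, 0.057, 0.076 and 0.040 without HF ZT12 replicates 7, 9 and 10 and KD ZT12 replicates 10 and 13, each with adjusted p between 0.075 and 0.20, and 0.112 without HF ZT12 replicate 13. At ZT0, acute phase genes were lower with HF donors (median -0.18, adjusted p = 0.00018, and adjusted p = 0.66 with an estimated correlation), and without KD ZT0 replicate 7, whose acute phase genes were far above those of the other arrays, the median was 0.00. By limma 0 genes passed at either time, with 681 at unadjusted p under 0.05 at ZT0 and 423 at ZT12.

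In gut at ZT0, the 5 genes named for the highest fold changes at unadjusted p under 0.001 for HF against NC donors were genes of cytotoxic lymphocytes, though none passed the threshold over all genes. Some genes above that p-value rose by more than all of these but Ccl5, such as Slc2a5 (0.82 ± 0.24) and Fbp1, an enzyme of glucose production (0.80 ± 0.28). The chemokine gene Ccl5 was 9.52 ± 0.39 with HF and 8.09 ± 0.27 with NC donors (mean log2 intensity ± SD, n = 4 arrays), a difference of 1.43 ± 0.24 with adjusted p = 0.12, and all 4 HF arrays lay above all 4 NC arrays. Cd8b1 and Cd8a, which encode the CD8 co-receptor, were at 0.63 ± 0.12 and 0.52 ± 0.13, the granule protein gene Nkg7 at 0.75 ± 0.14 and the granzyme Gzmk at 0.49 ± 0.10. Of 8 T and NK cell markers 7 were higher (median 0.52), and 3 rose adjusted over the list alone. The list had adjusted p = 5.4e-08, and adjusted p = 0.49 with an estimated correlation, and an unadjusted exact permutation p of 0.0286 for its mean, 7.52 ± 0.19 against 7.06 ± 0.20 (SD, n = 4 arrays). Interferon-stimulated genes were higher in 28 of 29 members (median 0.16, adjusted p = 3.1e-07, and adjusted p = 0.99 with an estimated correlation), with a median of 0.249 without HF ZT0 replicate 2. By limma 0 genes passed, with 931 at unadjusted p under 0.05. Over both times together Ccl5 rose by 1.17 ± 0.17 with HF donors (adjusted p = 0.014), the only gene called. No genes were called with an intensity trend, with the replicate block, or without 1 of 8 of the 16 arrays. With the mean of the B and plasma cell markers as a covariate, 3 genes rose for HF against NC donors at ZT0: Ccl5 (adjusted p = 0.014), Cd8b1 (adjusted p = 0.00048) and Nkg7 (adjusted p = 0.039). For KD donors at ZT0 0 genes passed by limma, with 784 at unadjusted p under 0.05. The T and NK cell markers had a median of 0.26 and MHC class II genes one of 0.41 (adjusted p = 0.0011 and 0.010, and adjusted p = 0.90 for both with an estimated correlation). Each rested on single arrays: the T and NK cell median was 0.10 without KD ZT0 replicate 1 (adjusted p = 0.24) and 0.463 without KD ZT0 replicate 5, and the MHC class II median was 0.17 without NC ZT0 replicate 6 and 0.221 without KD ZT0 replicate 1 (adjusted p = 0.46 and 0.31). HF against KD donors at ZT0 gave 0 genes by limma and 1076 at unadjusted p under 0.05, with Ccl5 at 1.02 ± 0.24 and Serpina1a, a secreted protease inhibitor, at -0.91 ± 0.22. Of the PPARγ list, Plin2 (-0.31 ± 0.09) passed in that comparison adjusted over the list alone, and 0 members over all genes.

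Among the largest donor differences in gut at ZT12 were those in B cell transcripts, whose levels were higher in NC recipients. Cd79a, a subunit of the B cell receptor, was 9.72 ± 0.63 with NC, 6.61 ± 1.81 with HF and 5.78 ± 0.30 with KD donors (mean log2 intensity ± SD, n = 4 arrays). For KD against NC donors the differences were -3.94 ± 0.97 for Cd79a, -3.88 ± 0.99 for Ms4a1, which encodes CD20, -3.60 ± 0.90 for the complement receptor Cr2 and -3.47 ± 0.77 for the follicle chemokine Cxcl13, each with adjusted p = 0.11. These SE pool the spread of 6 groups. The SD of Cd79a reached 1.96, in NC recipients at ZT0, so the SE and adjusted p do not measure the smaller spread of the 2 groups compared. Ms4a1 was at 5.15 with KD donors, near its level of 5.20 in liver, so low signal may limit the size of the differences. All 7 B and plasma cell markers were lower (median -2.49), and 6 fell adjusted over the list alone. The list had adjusted p = 8.5e-11, adjusted p = 0.28 with an estimated correlation and adjusted p = 0.086 by fry. Its mean was 6.68 ± 0.10 with KD and 8.89 ± 0.38 with NC donors (SD, n = 4 arrays), with an exact permutation p of 0.0286. Saa1, an antimicrobial acute phase gene, was at -3.43 ± 1.44 for KD against NC donors and did not pass (adjusted p = 0.42). The mean of 24 intestinal antimicrobial genes was 10.13 ± 0.11 against 10.57 ± 0.17 and that of 8 myeloid cell markers 8.02 ± 0.10 against 8.33 ± 0.09 (SD, n = 4 arrays), each with an exact permutation p of 0.0286, not adjusted over the lists. The medians of these lists were -0.06 and -0.15, with adjusted p = 0.081 and 0.13. All 7 MHC class II genes were lower (median -0.50, adjusted p = 0.00031, and adjusted p = 0.76 with an estimated correlation), at a median of -0.325 without KD ZT12 replicate 10. For HF against NC donors the B and plasma cell list's median was -1.82, with 5 members falling adjusted over the list alone and an exact permutation p of 0.0571 for its mean, and that of 7 MHC class II genes was -0.74, with 6 falling adjusted over the list alone. The adjusted p was 1.6e-05 and 5.4e-06, and adjusted p = 0.92 for both with an estimated correlation. In the 4 other gut groups the markers varied between arrays of 1 group, Cd79a by as much as 3.82, with HF ZT12 arrays between 5.46 and 9.28.

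**Figure D3:**
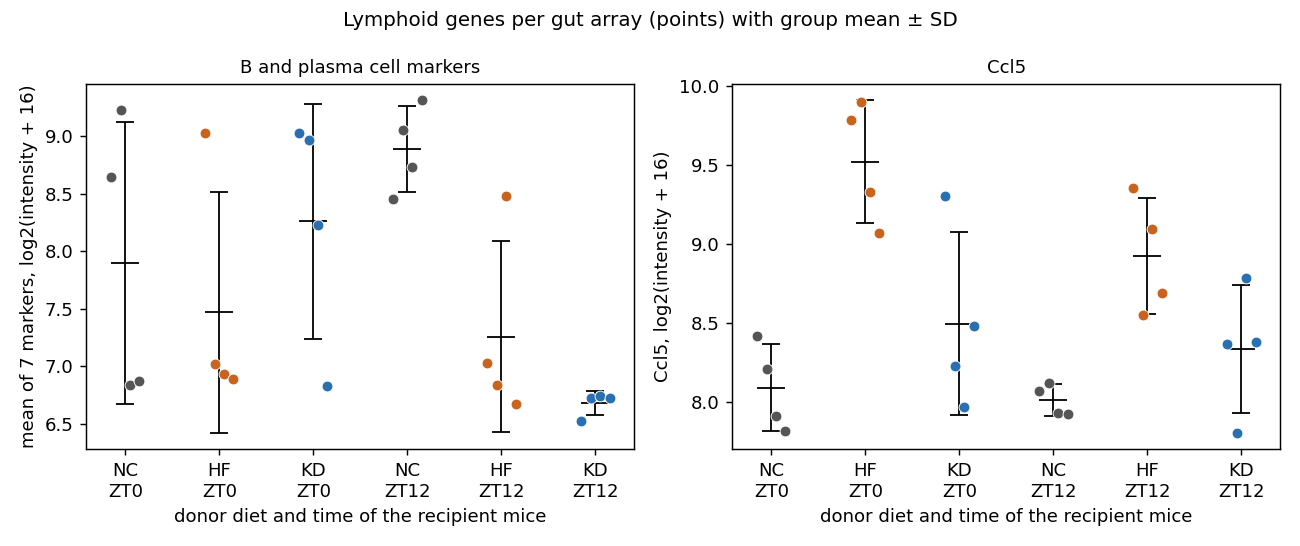
Mean of the 7 B and plasma cell markers (left) and Ccl5 (right) in each gut array (points; vertical axis log2(intensity + 16)) by donor diet and time, with group mean and SD. The 4 NC arrays of ZT12 lie high in B and plasma cell markers, at a mean of 8.89, and the 4 KD arrays of ZT12 low, at 6.68, while the 4 HF arrays of ZT0 lie above all NC arrays of ZT0 in Ccl5, at a mean of 9.52 against 8.09.

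A single gene passed over all genes for KD against NC donors at ZT12 in gut: Nfkbid (transcript cluster 10551891), a nuclear regulator of NF-κB, fell by 0.61 ± 0.09 (adjusted p = 0.0063), with all 4 KD arrays below all 4 NC arrays. Nfkbid was 5.96 ± 0.09 with KD, 6.12 ± 0.14 with HF and 6.57 ± 0.11 with NC donors (mean log2 intensity ± SD, n = 4 arrays). With the mean of the B cell markers as a covariate the KD difference was smaller but remained, at -0.37 ± 0.08 with adjusted p = 0.80. KD arrays (6.52 to 6.74) and NC arrays (8.45 to 9.31) do not overlap in that mean. The covariate therefore cannot part B cell content from donor diet here. Cholesterol synthesis genes were higher with KD than with NC donors in 21 of 22 members (median 0.19) and PPARα targets and fatty acid oxidation genes in 20 of 26 (median 0.11). The lists had adjusted p = 0.00023 and 0.0039, and adjusted p = 0.76 for both with an estimated correlation. The number of genes at unadjusted p under 0.05 was 1968 for KD and 1943 for HF, of which 0 passed for HF by limma. The KD count differed between settings: 453 genes (66 higher and 387 lower) passed when only the 2 groups, both uniform in B cell markers, were fitted, 255 with array weights, 24 with the replicate block, 445 from the authors' table values with the 2 groups alone fitted, and 0 with the covariate, without dim genes, or without NC ZT12 replicate 10 or 12 or KD ZT12 replicate 12 or 13. The filter on dim genes may have removed Nfkbid itself. Between HF and KD donors at ZT12, all 22 cholesterol synthesis genes were lower with HF donors (median -0.20), with Lss at -0.59 ± 0.18, and 21 of 23 cell cycle genes were lower (median -0.13), of which 4 fell adjusted over the list alone. Their adjusted p was 4.9e-11 and 6.0e-07, and adjusted p = 0.85 for both with an estimated correlation. The cell cycle median was -0.063, -0.252, -0.020 and -0.075 without HF ZT12 replicates 8, 10 and 12 and KD ZT12 replicate 12, with adjusted p = 0.071 without HF ZT12 replicate 12. Fgf15, an ileal hormone that represses bile acid synthesis, was at -1.39 ± 0.49. By limma 0 genes passed in that comparison, with 756 at unadjusted p under 0.05.

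**Figure D4:**
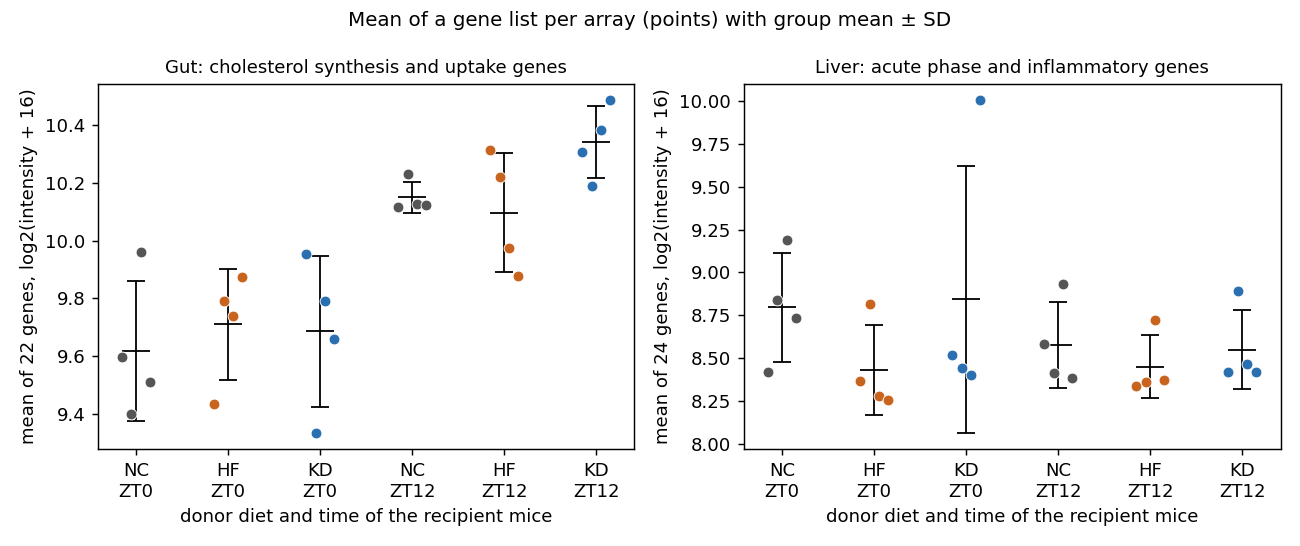
Mean of 22 cholesterol synthesis genes in each gut array (left) and of 24 acute phase genes in each liver array (right), as points (vertical axis log2(intensity + 16)) by donor diet and time, with group mean and SD. The cholesterol synthesis means are higher at ZT12 than at ZT0 for each donor diet, and a single KD array of ZT0, replicate 7, lies far above the other liver arrays in acute phase genes.

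Whether a donor effect changed between ZT0 and ZT12 was tested as the difference of the 2 effects. No clock gene passed. In liver the clock genes lay between Bhlhe40 at -0.61 ± 0.35 and Nfil3 at 0.36 ± 0.22 for HF, and between Bhlhe40 at -0.68 ± 0.35 and Ciart at 0.35 ± 0.24 for KD donors. In gut they lay, for KD donors, between Cry1 at -0.36 ± 0.19 and Ciart at 0.53 ± 0.23. The PPARγ list had liver medians of 0.07 for HF and -0.03 for KD donors, with 0 members past the threshold, also adjusted over the list alone. By limma 0 liver genes passed, with 598 at unadjusted p under 0.05 for HF and 845 for KD donors. The macrophage receptor Marco was at 1.33 ± 0.43 and the heat shock gene Hspb1 at -0.63 ± 0.19 for KD donors, and the heat shock list had a median of -0.22 (adjusted p = 0.0044, and adjusted p = 0.57 with an estimated correlation). Without NC ZT0 replicate 5 or KD ZT0 replicate 3 that median was -0.187 and -0.155, with adjusted p = 0.065 and 0.091. In gut, 0 genes passed for HF donors (823 at unadjusted p under 0.05) and 1 for KD donors (1376): the olfactory receptor Olfr192, at 0.90 ± 0.14 with adjusted p = 0.022 and group means from 4.48 to 5.18, was named after its value was seen. The count was 0 under 6 other settings, 149 with the replicate block, and 0 without 1 of 11 of the 16 arrays. The filter on dim genes, among those settings, removes Olfr192 itself. B and plasma cell markers had a median of -2.95 for KD donors, with 6 of 7 falling adjusted over the list alone (adjusted p = 8.7e-10, and adjusted p = 0.38 with an estimated correlation), and Cd79a was at -4.64 ± 1.37. For HF donors the T and NK cell markers had a median of -0.35 and the interferon-stimulated genes one of -0.20 (adjusted p = 6.0e-05 for both, and adjusted p = 0.87 for both with an estimated correlation), the latter at -0.119 without HF ZT12 replicate 12. For no list in any contrast did the median and the test differ in sign.

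The effects of HF and KD donors, set against each other across genes, share their NC arrays and so correlate without any effect. The correlation across genes was 0.561 in liver at ZT0, where unchanged groups simulated with shared NC arrays gave 0.50, and 0.618 against 0.502 at ZT12. In gut it was 0.272 against 0.497 at ZT0 and 0.828 against 0.499 at ZT12, where the B and plasma cell markers were lower with both donor diets. The simulation drew errors independently for each gene, which by construction sets its value near 0.50. In real arrays many genes move together, which can move the correlation either way. A value above the simulated one therefore does not show a shared donor effect. With the 4 NC arrays parted into 2 and 2, so that the donor diets shared none, the correlations were 0.012 and 0.168 in liver and -0.274 and 0.577 in gut.

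The authors' deposited tables list p-values for the same 8 donor comparisons. At ZT0 their p-value column was under 0.05 for 614 clusters for HF and 619 for KD in gut, and for 1268 and 346 in liver. At ZT12 it was so for 2071 and 2991 in gut, and for 2616 and 2256 in liver. Adjusted by Benjamini-Hochberg, 210 and 662 gut clusters at ZT12 and 2 and 2 liver clusters at ZT12 were under 0.05, and 0 in each table of ZT0. The direction of the deposited ratio was that of the limma fold change for 83.5% to 95.0% of genes. Of the liver clusters under 0.05 at ZT12, 2181 for HF and 1781 for KD were higher. Liver array medians at ZT12 were 98.05 to 104.39 (HF) and 98.85 to 102.80 (KD), all above the 93.17 to 97.22 of NC. The authors' tables hold values without the quantile step, after which limma had 927 and 827 genes at unadjusted p under 0.05. Whether array brightness accounts for the liver counts was not tested.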

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

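The tests of the quantile step and of B cells throughout the body, and the comparison with the lymphoid marker covariate, were chosen after the results were seen. Single arrays were picked where the gap to the nearest array of their group was large for the group's range, in 174 combinations of a group and 1 of 15 measures. The test picks about 1 in 20 groups by chance, and it picked 15.

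B and plasma cell markers were lower in gut of KD than of NC recipients at ZT12, with a mean difference of -2.21, and the same held in direction for HF recipients. On the values as deposited the list's median was -2.47, which argues against the added quantile step; the authors' own normalization was not tested. Lymphoid tissue present in some gut pieces and not in others may account for the pattern: of 703 other genes at unadjusted p under 0.01, 79.9% had the sign given by the slope on the markers within the 4 other gut groups, where 51.0% did among genes at p of 0.5 or more. The fold changes followed that slope at r = 0.908 across genes, but the sign share fell just short of the level set in advance, and all 4 arrays of each group lay on 1 side, so a donor effect on lymphoid cells and uneven sampling cannot be told apart. A loss of B cells throughout the body cannot be told apart either: in liver the list's median was 0.067, but its markers were dim there, at a median of 5.73 against 7.12 for all genes.

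Liver KD ZT0 replicate 7 stood apart: its mean correlation with its group was 0.975 (nearest 0.983), its acute phase mean 10.005 (nearest 8.516), and 176 genes lay at least 2-fold from the 11 other ZT0 arrays, where the others had 17 to 57. Mt2 (6.09 above), Lcn2 (5.39), Orm2 (5.28), Saa2 (4.73) and Saa1 (4.44) led, and 17 of 24 acute phase genes lay above every other ZT0 array. RNA of pancreas, fat, gut epithelium or gut wall is not favoured, since the median deviations of 4 marker lists of non-liver cells, which it would raise, reached 0.10 at the highest and -0.2 at the lowest, and neither is a dim array, since the median intensity of 101.3 lay inside the other arrays' range. The reference arrays were uneven in gut markers. Their absorptive enterocyte mean reached 9.402, in NC ZT0 replicate 5, against 8.696 in replicate 7, and Reg3b reached 11.923 against 6.093. The -0.2 therefore depends on the reference, and gut RNA in the other ZT0 liver arrays was not tested. Liver macrophage and myeloid cell markers were raised in replicate 7, with median deviations of 0.543 and 0.513 beside 0.6 for the acute phase genes, so more cells of these types stay open. An acute phase response in this mouse is a candidate explanation; no group of the design gives one, and no biological explanation was tested.

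Other arrays picked by the same test are given as values. Gut HF ZT0 replicate 1 had a median intensity of 131.6 (nearest 125.3), an MHC class II mean of 10.467 (nearest 9.193) and a B and plasma cell mean of 9.034 (nearest 7.02). Gut KD ZT12 replicate 10 had a mean correlation of 0.992 with its group, and liver HF ZT12 replicate 7 of 0.993. The B and plasma cell mean was 6.524 in gut KD ZT12 replicate 8 (nearest 6.724) and 5.724 in liver NC ZT0 replicate 6 (nearest 5.90). The mean of the PPARγ list was 7.959 in gut NC ZT0 replicate 6 (nearest 8.592), 8.102 in liver HF ZT12 replicate 13 (nearest 8.279) and 8.239 in liver NC ZT12 replicate 13 (nearest 8.152). The cholesterol synthesis mean was 10.232 in gut NC ZT12 replicate 10 (nearest 10.128). The acute phase mean was 8.722 in liver HF ZT12 replicate 10 (nearest 8.37) and 8.892 in liver KD ZT12 replicate 10 (nearest 8.465).

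Olfr192 was singled out because its KD donor effect in gut differed between the times by 0.90 on the log2 scale. Clusters without a gene name, which the comparisons of the report do not use, passed the threshold in liver between ZT12 and ZT0 (296 with NC, 208 with HF and 217 with KD donors), in gut between the times (72, 134 and 147), and in liver for HF against NC donors at ZT0 (1).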

How the results depend on the processing

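The lymphoid marker covariate in gut, every comparison over both times together and the lists without liver KD ZT0 replicate 7 were chosen after the data were seen; the other settings were planned. Unless a cause is named, the cause was not tested. In liver the time counts kept within 1.5 times their value without any 1 array, and by limma no clock gene or PPARγ gene passed over all genes between donor diets in either tissue, on values as deposited, without dim genes, with the replicate block, with the lymphoid covariate or without any 1 array. These 2 lists were not counted under the other settings. Among those are only the groups compared, array weights and the authors' table values, which called many more genes for gut KD against NC at ZT12. By the authors' p-values with Benjamini-Hochberg adjustment Aqp7 passed for KD against NC donors in gut at ZT12 (adjusted p = 0.034), and in the report Cidec and Plin2 passed between HF and KD donors adjusted over the list alone. Genes of low signal limit what the arrays show: without dim genes 12069 genes were tested in liver and 11851 in gut. In each sentence the settings' values replace those of the report.

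Of genes called (value of the report first), liver KD against NC at ZT12 went from 0 to 1 with an offset of 1 and to 1 with array weights, and liver HF against NC at ZT0 from 0 to 1 with all clusters singly, which tests more clusters. Time differences in liver went from 1790 to 806 for KD donors when only the groups compared were fitted, and from 1882 to 3178 for NC and 1626 to 2464 for HF donors with array weights. In gut they went from 494 to 173 for NC and 687 to 190 for HF donors when only the groups compared were fitted, and from 826 to 1382 for KD donors with array weights. Gut KD against NC at ZT12, 1 in the report, was 453 with only the groups compared, 255 with array weights, 445 with the authors' table values, 24 with the replicate block and 0 without dim genes. The filter on dim genes may have removed Nfkbid, the gene called. The counts of 453 and 445 come from fits of the 2 groups alone, which leave out the larger spread of the other groups. The change of the KD effect in gut, 1 in the report, was 0 on values as deposited, 0 without dim genes, 0 with an offset of 1, 0 with only the groups compared and 0 with all clusters singly. The filter on dim genes removes Olfr192, the gene called, so it did not retest that call. Over both times, liver KD against NC, 1 in the report, was 0 as deposited, 0 without dim genes, 0 with only the groups compared and 0 with a trend and robust prior; gut HF against NC, 1, was 0 with a trend and robust prior; gut KD against NC, 0, was 4 with only the groups compared.

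With a block for the replicate number, which the pairing check gave no ground for, liver time counts were 383 for NC, 288 for HF and 348 for KD donors, gut KD against NC at ZT12 gave 24 genes and the change of the KD effect in gut 149, and over both times liver KD against NC gave 0, liver HF against KD 1 and gut HF against NC 0. The block fit could not be run for the time differences in gut, where no number occurs at both times. In liver a single ZT0 array, KD ZT0 replicate 7, has a number that recurs at ZT12. The blocked time differences in liver, and the lists and genes that turn in them, rest on that array. Lists called went from 9 to 4 for liver HF against NC at ZT0, 5 to 2 at ZT12, 7 to 4 for liver HF against KD at ZT0, 0 to 4 and 2 to 4 for the change of the HF and KD effects in liver, 2 to 5 for gut HF against NC at ZT12, 7 to 12 for gut HF against KD at ZT0 and 4 to 11 for the change of the KD effect in gut. Clock genes called in liver with NC donors went from 19 to 12, and PPARγ genes from 3 to 1 with NC, 3 to 0 with HF and 3 to 0 with KD donors. List medians that turned were, in liver, fatty acid and triglyceride synthesis for HF at ZT0 (-0.055), cholesterol synthesis for HF at ZT12 (-0.020) and sinusoidal endothelium between the times (0.259 with NC, 0.102 with HF and 0.040 with KD donors), and in gut cholesterol synthesis for KD at ZT0 (-0.061), enteroendocrine cells for KD at ZT0 (-0.011) and cholesterol synthesis in the change of the HF effect (0.007). Single genes that turned in liver between the times were Baat (0.049), Gsr (0.016), Klf4 (-0.164), Oit3 (0.181) and Lgr5 (0.113) with NC, Nr1i2 (-0.014), Foxo1 (-0.185) and Il1b (0.429) with HF, and Oit3 (0.009) and Lgr5 (0.017) with KD donors.

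Lists called by camera changed on values as deposited from 0 to 2 for the change of the HF effect in liver and from 2 to 1 for that of the KD effect. Without dim genes, which leaves fewer genes to compare with, they went from 5 to 8 for liver HF at ZT12, 8 to 4 for liver KD at ZT0, 0 to 3 and 2 to 4 for the change of the HF and KD effects in liver, and 6 to 3 for the change of the HF effect in gut. With an estimated correlation, which widens the test, 0 lists were called in each donor comparison and in each change of a donor effect, 1 list in the time differences of liver for NC, 1 for HF and 1 for KD donors, 1 and 1 in gut for NC and HF donors, and 0 for KD donors. By fry 0 lists were called in each donor comparison and each change of a donor effect, and 3, 5 and 3 in the time differences of gut for NC, HF and KD donors. PPARγ genes called between the times in gut were 2 with KD donors as deposited, and 1, 1 and 2 with NC, HF and KD donors without dim genes.

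With the lymphoid covariate in gut, 3 genes were called for HF against NC at ZT0, 0 for KD against NC at ZT12, 1 for HF against KD at ZT0, 354 between the times with KD donors, 0 for the change of the KD effect, and over both times 2 for HF against NC and 1 for HF against KD; lists went from 2 to 11 for HF at ZT12, 9 to 5 for KD at ZT0 and 4 to 2 for the change of the KD effect. Genes at unadjusted p under 0.01 fell from 709 to 244 for KD against NC at ZT12 and from 550 to 204 for HF. Medians that turned were MHC class II (0.335) and B and plasma cell markers (0.025) for KD at ZT12, B and plasma cell markers for HF against KD at ZT0 (0.007) and ZT12 (-0.013), T and NK cell markers between the times with KD donors (0.015), and MHC class II (0.079) and T and NK cell markers (0.066) in the change of the KD effect; the covariate removes the B cell markers by construction. PPARγ genes between the times in gut were 1 with HF and 0 with KD donors.

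Leaving out 1 array at a time, genes called ranged in gut from 287 to 548 between the times with NC donors, 311 to 1022 with HF donors and 349 to 817 with KD donors, from 0 to 2 for HF against NC at ZT0, 0 to 1 for KD against NC at ZT12 and 0 to 1 for the change of the KD effect, and over both times from 0 to 1 for HF against NC and 0 to 1 for HF against KD in gut, and 0 to 1 for HF and 0 to 2 for KD against NC in liver. PPARγ genes in gut ranged from 0 to 1, 0 to 2 and 0 to 1 between the times with NC, HF and KD donors. Lists called in liver ranged from 2 to 12 and 2 to 6 for HF against NC at ZT0 and ZT12, 2 to 11 and 1 to 7 for KD against NC, 0 to 7 and 3 to 8 for HF against KD, 4 to 11 and 7 to 15 between the times with NC and KD donors, and 0 to 6 and 0 to 8 for the change of the HF and KD effects. In gut they ranged from 2 to 10 and 2 to 7 for HF against NC at ZT0 and ZT12, 4 to 15 and 6 to 11 for KD against NC, 4 to 9 and 4 to 11 for HF against KD, 7 to 15 and 8 to 13 between the times with HF and KD donors, and 3 to 9 for the change of the KD effect. Medians that turned in liver for HF at ZT0 were fatty acid and triglyceride synthesis (-0.026 to 0.225, low without HF ZT0 replicate 2), intestinal antimicrobial genes (-0.159 to 0.013) and myeloid cells (-0.23 to 0.014), both high without NC ZT0 replicate 5; for HF against KD at ZT0 they were PPARα targets (-0.014 to 0.219) and acute phase genes (-0.251 to 0.00), turned without KD ZT0 replicate 7. In gut they were, for KD at ZT0, cholesterol synthesis (-0.017 to 0.190) and interferon-stimulated genes (-0.039 to 0.134), both low without KD ZT0 replicate 1, and cell cycle genes (-0.158 to 0.026, high without NC ZT0 replicate 4), and nutrient absorption between the times with HF donors (-0.042 to 0.136, low without HF ZT12 replicate 12 or HF ZT0 replicate 5).

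Of the authors' p-values, those under 0.01 numbered in gut 136 and 716 for HF at ZT0 and ZT12 and 130 and 1300 for KD, and in liver 311 and 617 for HF and 55 and 638 for KD; Benjamini-Hochberg left 0 and 210, 0 and 662, 0 and 2, and 0 and 2, stricter by construction. With the NC arrays parted so that HF and KD shared none, the correlation of the effects across genes was 0.012 and 0.168 in liver and -0.274 and 0.577 in gut, where shared arrays add to it by construction.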

Other observations

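The test of the place of the gut pieces, and all results over both times together, were chosen after the results were seen.

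Genes that vary along the intestine varied between gut arrays of 1 group. Lct, the lactase of the upper small intestine, spanned as much as 6.07 on the log2 scale within a group, and Saa1, an antimicrobial acute phase gene, as much as 5.99. Taken as deviations from the group means over 24 gut arrays, Saa1 was inversely related to Lct with Pearson r = -0.793 (permutation p = 0.00187, adjusted p = 0.0131) and Spearman rho = -0.786 (p = 0.00165), and r = -0.743 without the 2 arrays farthest from the median. With nutrient absorption genes r was -0.715 (permutation p = 0.00583, adjusted p = 0.0204) and rho -0.658 (p = 0.00853), with r = -0.638 without 2 arrays. With duodenal and jejunal enterocyte markers r was -0.523 (permutation p = 0.0213, adjusted p = 0.0497) and rho -0.556 (p = 0.0167), with r = -0.503 without 2 arrays, among 7 relations computed. With ileal enterocyte markers r was -0.039 (permutation p = 0.866; -0.304 without 2 arrays), with colon epithelium markers 0.266 (p = 0.233; 0.488 without 2 arrays) and with B and plasma cell markers -0.144 (p = 0.612; 0.136 without 2 arrays). Pieces taken from different places along the gut may account for part of this, by the value of -0.523, but over all arrays the ileal and colon markers did not follow Saa1 beyond chance, and a local change that lowers absorptive genes was not tested. An inflammation shared by gut and liver of the same mouse is not favoured: over the 15 mice with both arrays, r of Saa1 between the tissues was -0.259 (permutation p = 0.354, adjusted p = 0.496) and rho -0.357 (p = 0.192), r was -0.642 without 2 mice, and the bound set in advance for that explanation was a positive relation.

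Over both times together, B and plasma cell markers were lower in gut of KD and of HF than of NC recipients (medians -0.95 and -1.09, adjusted p = 2.4e-05 and 0.00050, and adjusted p = 0.65 and 0.95 with an estimated correlation). For KD donors this pools times that differ: the marker mean was 8.26 with KD and 7.90 with NC donors at ZT0, and 6.68 and 8.89 at ZT12, so the lower level was at ZT12 alone. For HF donors MHC class II (-0.39) and heat shock genes (-0.14) were lower and T and NK cell markers (0.25) and interferon-stimulated genes (0.07) higher, with adjusted p = 0.00091, 0.0030, 0.0073 and 0.034, and adjusted p = 0.95 for each with an estimated correlation. Pooling hides the time for HF donors too. By the means per array, the T and NK cell and interferon differences lay mostly at ZT0. The MHC class II difference lay mostly at ZT12. KD recipients had higher gut medians than NC recipients for PPARα targets (0.12) and cholesterol synthesis (0.14) and for enteroendocrine markers (0.16), with adjusted p = 3.2e-05, 2.4e-05 and 0.00025, and adjusted p = 0.65 for each with an estimated correlation. Hepatocyte markers (0.26), drug metabolism (0.13) and goblet cell markers (0.07) were higher as well and heat shock (-0.09) and unfolded protein response genes (-0.05) lower, with adjusted p = 0.0052, 0.032, 0.045, 0.015 and 0.0045; with an estimated correlation it was 0.79 for drug metabolism and 0.65 for the other 4. In liver, fatty acid and triglyceride synthesis had medians of 0.14 with HF and 0.14 with KD donors (adjusted p = 9.0e-05 and 6.7e-05, and adjusted p = 0.65 and 0.78 with an estimated correlation), and cholesterol synthesis 0.12 and 0.16 (adjusted p = 0.0027 and 6.7e-05, and adjusted p = 0.67 and 0.78 with an estimated correlation). With HF donors interferon-stimulated genes (-0.16), unfolded protein response genes (-0.10), acute phase genes (-0.14) and macrophage markers (-0.26) were lower, with adjusted p = 1.3e-06, 8.0e-05, 0.0049 and 0.00011, and adjusted p = 0.65 for each with an estimated correlation. Markers of sinusoidal endothelium were higher with HF and KD donors (0.16 and 0.10, adjusted p = 8.0e-05 and 0.034), and so were enteroendocrine markers (0.07 and 0.09, adjusted p = 0.019 and 0.00011). With an estimated correlation both lists had adjusted p = 0.65 and 0.78. The enteroendocrine markers, of a gut cell type, were dim in liver. Their mean per liver array lay between 6.31 and 6.64, against a median of 7.12 for all genes, so shifts of this size may lie in background signal.

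Other splits of the same arrays into groups of the same sizes were fitted alike, all 35 for 2 groups of 4 arrays and 100 drawn for larger sets. For the time differences in liver the real split called the most genes, 1882, 1626 and 1790 for NC, HF and KD donors, and the highest other split 48, 1 and 418. That is 1 of 35 splits each, the smallest share this test can give, not adjusted over the contrasts. It argues against chance but does not exclude it. In gut the same held for NC (494, highest other 8) and KD donors (826, highest other 1), each in 1 of 35. For HF donors in gut the count alone does not exclude chance: the real split called 687 genes and another 746, so 2 of 35 gave as many. Of the genes called, 151 higher and 129 lower were shared with NC donors, where 3.76 and 4.42 would be expected if the calls were independent, and 182 and 160 with KD donors (6.54 and 7.09 expected), from separate arrays. That expectation takes genes as independent, though many move together. The overlap was not computed for the other splits, so it does not settle whether chance is excluded.

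For the donor comparisons with a real count of 0 the splits decide nothing, since every split gives as many. The highest other counts in liver were 16 and 0 for HF against NC at ZT0 and ZT12, 27 and 0 for KD against NC, 147 and 1 for HF against KD, and 2 and 32 for the change of the HF and KD effects with time. In gut they were 1 and 1 for HF against NC, 149 for KD against NC at ZT0, 4 and 3 for HF against KD, and 80 for the change of the HF effect. For the counts of 1 chance is not excluded. The real count of 1 for KD against NC at ZT12 in gut was reached by 2 of 35 splits (highest other 1), and that of 1 for the change of the KD effect in gut by 5 of 100 (highest other 1). Over both times together, the real count of 1 for HF against NC in gut was reached by 8 of 100 (highest other 258) and that of 1 for KD against NC in liver by 7 of 100 (highest other 59); the others had real counts of 0 and highest others of 5 and 10 in liver, for HF against NC and HF against KD, and of 2 and 3 in gut, for KD against NC and HF against KD. Splits that called far more genes than the real one, with 147, 149 and 258 genes, point to a structure of the arrays that the groups do not hold.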
